A study of Bactrocera dorsalis with 16 samples.

How the data were processed

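Transcript levels were measured by RNA sequencing in adult females of the oriental fruit fly, Bactrocera dorsalis. Ovary and fat body were each sampled at 1, 5, 9 and 13 days after eclosion, with 2 libraries per tissue and age, 16 in all. Per the labels, total RNA was taken with Trizol and the libraries were read on an Illumina instrument. The deposited table gives FPKM, fragments scaled to transcript length and library size, for 13759 genes in 1 column per library. The authors' notes name HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 without saying which step each served. Their notes also name the genome build mm8, a mouse build that cannot be the fly's, and the fly assembly and annotation are not stated. No genomic positions are given here for that reason.

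Genes are named by the product in the table's description column together with the table's own gene identifier. The separate symbol column was not used: 62 genes were ribosomal proteins by description and 67 by symbol, with 0 shared, and the median level was 624.2 FPKM for the described set and 6.27 FPKM for the other. A description was present for 10449 genes and absent for 3310. Several genes can carry the same product name, as 1327 product names did. The depth of the libraries is not stated and read counts were not used here, so no counting interval can be given. From the most common ratio between low values of the same genes, relative depth ran from 0.866 to 1.103 of that of ovary day 1 replicate 1. Sums of FPKM ran from 290383 to 405928.

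Values were analysed as log2 of FPKM plus 1, as deposited, with no further scaling. The 10213 genes with a mean of at least 1 FPKM in at least 1 of the 8 groups were tested with limma 3.58.1 in R 4.3.3, with a variance trend and robust moderation, 1 coefficient per group and all 16 libraries in the fit. Because each group holds 2 libraries, the groups share 1 estimate of the spread of each gene. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as changed. Log2 fold changes are differences of means of log2 of FPKM plus 1, given with their standard error (SE), and levels are mean FPKM ± SD. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

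The comparisons were each age against the one before it within each tissue, the ovary against the fat body over the 4 ages, and the difference between the tissues in each age step, tested as an interaction. A set of 26 gene lists was defined by patterns in product names. The lists were yolk proteins, yolk uptake and endocytosis, chorion and vitelline membrane, germline and oogenesis, cell cycle and DNA replication, ecdysteroid synthesis, ecdysone response, juvenile hormone, insulin and TOR, small RNA machinery, fat body storage and lipid, sugar and energy metabolism, and oxidative phosphorylation. Further lists were cytosolic ribosomal proteins, proteasome, antimicrobial and immune recognition, detoxification, heat shock proteins, cuticle proteins, eggshell peroxidase and cross-linking, and maternal embryo patterning. The others were markers of muscle, neurons, gut, hemocytes, and spermatheca and accessory gland. Lists of at least 3 genes were tested with camera of limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals, and the p-values were adjusted over the lists of 1 comparison. The comparisons, the lists, the test and the rule for naming genes were fixed before the data were examined.

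The rule for naming genes had 3 parts. The first took, in each direction, the 6 changed genes with the largest fold change whose groups did not overlap, with a mean of at least 10 FPKM in the higher group and an informative product name. The next took up to 3 members with the smallest p from each list with a changed member. The last took the vitellogenins, the vitellogenin receptor, vasa, oskar and nanos. A product name already taken was not taken again in the first part. Of the genes so named, the text gives ones whose call held when any 1 library was left out and under the other alternatives, apart from the fits to only the groups compared and the subtraction of an ovarian share. The exceptions are 2 vitellogenins in the last step in the ovary and 1 in the last step in the fat body, whose values are given. That narrowing was made after the data were seen. Differences between the tissues are given for the genes named in the same step of both and for 6 more pairs of gene and step chosen after their values were seen, with no such narrowing.

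The alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization and fits to only the groups compared. Others were limma without trend and robust moderation, a term or a random block for the replicate number, an added 2-fold threshold (1 on the log2 scale), and each of the 16 libraries left out in turn. Replicate numbers were tested for pairing. Over the 28 pairs of groups the deviations of like-numbered libraries correlated between -0.149 and 0.146 across genes. Between ovary and fat body of the same age the correlation ran from 0.016 to 0.083. The random block by age and number had a consensus correlation of 0.122. In the main fit the numbers were not treated as pairs. The test was also run once per comparison on simulated data. There all groups shared each gene's mean over all libraries and 1 spread, and 200 of 10213 genes were changed. In the age steps it recovered 23% to 33% of genes changed 2-fold and 59% to 73% of genes changed 4-fold, and in the tissue comparison 65% and 90%. In the data more genes were called and the spread between replicates varied by group, so these shares and the next need not hold there. Genes simulated as unchanged made up 2.4%, 5.5% and 5.7% of the calls in the ovary steps, 7.6%, 3.3% and 8.2% in the fat body steps and 3.7% in the tissue comparison, so that share was above 5% in 4 of the 6 age steps. Carry-over of ovarian RNA was followed with 79 genes that had at least 50 FPKM in the ovary at day 9 and a mean in the fat body of days 1 and 13 of at most 1% of that level, a set chosen after the data were seen. Their median share was subtracted from the fat body libraries in 1 added alternative, and the fat body libraries of day 9 were left out in another.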

Results

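Transcript levels were compared in ovary and fat body of adult female oriental fruit flies. The fat body is the insect organ that stores nutrients and makes yolk precursors, and the ovary takes them up. The 16 libraries formed 8 groups of 2, for ovary and fat body at days 1, 5, 9 and 13 after eclosion. Between 7425 and 9054 genes reached at least 1 FPKM in a library. The first principal component held 61.1% of the variance and set all ovary libraries apart from all fat body libraries, and the second held 14.9%. Across genes, which are not independent replicates, the libraries of a group correlated at r between 0.919 (ovary day 1) and 0.966 (ovary day 13). Since total read counts are unknown, a level of 0 sets no stated limit. Levels are mean FPKM ± SD with n = 2 unless another n is given, and changes are log2 fold changes ± SE.

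The comparison of the tissues asked which transcripts mark each organ over the 4 ages. Germline and cell-division transcripts were higher in the ovary. Vasa (MSTRG.707), a germline RNA helicase, lay at 490.4 ± 73.2 FPKM in ovary and 15.67 ± 5.42 FPKM in fat body (n = 8 each; 4.93 ± 0.11). G2/mitotic-specific cyclin-B (MSTRG.8707, 5.65 ± 0.20), the transcription factor ovo (MSTRG.1919, 5.42 ± 0.10), the translational repressor nanos (MSTRG.1614, 4.96 ± 0.14), protein cup (MSTRG.2454, 3.34 ± 0.07) and an insulin-like peptide receptor (MSTRG.5296, 5.02 ± 0.13), which senses nutrition, were higher there too. Actin-5, muscle-specific (MSTRG.7529, -6.84 ± 0.17), the odorant-binding proteins 56d-like (MSTRG.2522, -6.78 ± 0.22) and 19d-like (MSTRG.1178, -6.38 ± 0.11) and cuticle protein 7 (MSTRG.3011, -5.94 ± 0.14) were higher in the fat body.

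By list, 31 of 33 cell cycle and DNA replication genes were higher in the ovary and 0 lower, among them the replication licensing factor Mcm3 (MSTRG.169, 3.21 ± 0.07). Camera gave the list an adjusted p of 2.6e-06, and an adjusted p = 0.0632 with an estimated correlation. Of 19 germline and oogenesis genes, 18 were higher and 1 lower (adjusted p 0.00189; adjusted p = 0.13 with an estimated correlation). The chorion and vitelline membrane list had 9 of 11 higher and 2 lower, and the lower ones are products named chorion peroxidase, such as MSTRG.8817 (-4.29 ± 0.08), whereas chorion peroxidase MSTRG.6306 was higher (4.77 ± 0.13). Juvenile hormone epoxide hydrolase 1-like (MSTRG.9415), of a family that breaks down juvenile hormone, was higher in the ovary (4.39 ± 0.11). So were nuclear hormone receptor HR78 (MSTRG.5229, 2.21 ± 0.12), exportin-5 (MSTRG.10548, 1.99 ± 0.11), which carries microRNA precursors out of the nucleus, and the cell-cycle regulator plutonium (MSTRG.4116, 3.89 ± 0.10). The chorion list did not pass (adjusted p 0.485), nor did yolk uptake and endocytosis (adjusted p 0.159) or ecdysteroid synthesis (adjusted p 0.251). Higher and lower members numbered 11 and 1 of 13 for yolk uptake and endocytosis, 4 and 0 of 7 for ecdysteroid synthesis, 15 and 2 of 18 for ecdysone response, and 7 and 0 of 9 for small RNA machinery. Insulin and TOR had 13 and 0 of 15 (adjusted p 0.0223; adjusted p = 0.352 with an estimated correlation). Juvenile hormone had 3 and 2 of 6 (adjusted p 0.819), with a mean fold change of 0.93, camera's direction down and a median that went from 0.40 as deposited to -0.29 under median-of-ratios scaling. Neuron markers had 11 and 2 of 16, with CUGBP Elav-like products, RNA-binding proteins not limited to neurons, among the higher ones, and heat shock proteins 10 and 2 of 16. Neither of these lists passed (adjusted p 0.392 and 0.608), and their medians of 0.66 and 0.70 went to 0.12 and 0.03 under median-of-ratios scaling, where camera's direction for heat shock proteins turned down. As deposited, the ecdysone response and small RNA lists had an adjusted p of 0.195 and 0.0656. It was 0.0327 and 0.119 under median-of-ratios scaling, 0.0371 and 0.0143 under quantile normalization, and 0.629 and 0.388 with an estimated correlation.

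The lists of metabolism, defence and integument pointed to the fat body libraries. Of 95 detoxification genes 65 were lower in the ovary and 15 higher, as in probable cytochrome P450 4ac1 (MSTRG.7932, -4.33 ± 0.09) and 28d1 (MSTRG.2247, -4.53 ± 0.11), and of 42 cuticle genes 36 were lower and 3 higher. Both calls had an adjusted p of 0.00556 with the estimated correlation. Sugar and energy metabolism had 28 of 47 lower and 10 higher, with a trehalose-phosphate synthase (MSTRG.7927, -4.63 ± 0.11), and maternal embryo patterning had 18 of 29 lower and 8 higher. Both kept an adjusted p of 0.0127 with the estimated correlation. The embryo patterning genes that were lower include products named after the serine proteases easter and snake. Storage and lipid genes had 26 of 33 lower and 3 higher, as in lipid storage droplets surface-binding protein 1 (MSTRG.10985, -3.97 ± 0.09) and long-chain fatty acid transport protein 4-like (MSTRG.10032, -3.84 ± 0.08). The list test gave an adjusted p of 9.55e-11, and an adjusted p = 0.0533 with an estimated correlation. Immune genes had 26 of 31 lower and 3 higher, as in CD109 antigen-like (MSTRG.9917, -4.60 ± 0.11) and gram-negative bacteria-binding protein 1 (MSTRG.3066, -4.37 ± 0.11). The list test gave an adjusted p of 1.96e-08, and an adjusted p = 0.0632 with an estimated correlation. Of the yolk proteins 4 of 9 were lower in the ovary and 0 higher (adjusted p 0.0223; adjusted p = 0.106 with an estimated correlation), with vitellogenin-2-like (MSTRG.3414) at -1.37 ± 0.08 and vitellogenin-1-like precursor (MSTRG.3415) at -1.42 ± 0.11. That list call ended under median-of-ratios scaling (adjusted p 0.0553) and quantile normalization (adjusted p 0.166). Low-density lipoprotein receptor-related protein 2-like (MSTRG.7759, -4.64 ± 0.12) was lower as well. Muscle markers had 27 of 32 lower and 3 higher (adjusted p 9.17e-10; adjusted p = 0.0765 with an estimated correlation). Gut markers had 22 of 38 lower and 6 higher (adjusted p 5.65e-05; adjusted p = 0.106 with an estimated correlation). Hemocyte markers had 7 of 10 lower and 3 higher (adjusted p 0.01; adjusted p = 0.0632 with an estimated correlation), as in croquemort-like MSTRG.2919 (-4.34 ± 0.12). Eggshell peroxidase and cross-linking had 13 of 20 lower and 5 higher (adjusted p 0.000642; adjusted p = 0.106 with an estimated correlation). Oxidative phosphorylation had 24 of 45 lower and 10 higher (adjusted p 0.00139; adjusted p = 0.352 with an estimated correlation). Its call also ended under quantile normalization, with a median that went from -0.28 to 0.00 and an adjusted p of 0.442, against 0.000115 under median-of-ratios scaling. Spermatheca and accessory gland, too short for the list test, had 1 of 2 lower. Cytosolic ribosomal proteins had 36 of 58 higher and 0 lower and the proteasome 10 of 19 and 0, but their median fold changes of 0.34 and 0.43 turned to -0.51 and -0.41 under median-of-ratios scaling. The proteasome list did not pass (adjusted p 0.608), and the ribosomal list did not pass as deposited (adjusted p 0.601; adjusted p = 0.881 with an estimated correlation). It passed downward under median-of-ratios scaling (adjusted p 0.000338) and upward under quantile normalization (adjusted p 1.58e-06). Adjusted over the list alone, the higher and lower counts were 16 and 2 for ecdysone response, 9 and 22 for oxidative phosphorylation, 34 and 0 for ribosomal proteins, 3 and 37 for cuticle and 11 and 3 for neuron markers, and those of the other lists were as above.

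In limma, 8402 of 10213 genes differed between the tissues, 5860 higher and 2542 lower in the ovary. The median fold change of all genes was 0.58 as deposited, 0.01 under median-of-ratios scaling and 0.21 under quantile normalization, while the percentage of changed genes that were higher in the ovary went from 69.7% to 50.3% and 58.2%. Directions between the tissues are therefore relative to that shift. With a 2-fold threshold added, 5337 genes differed.

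**Figure D1:**
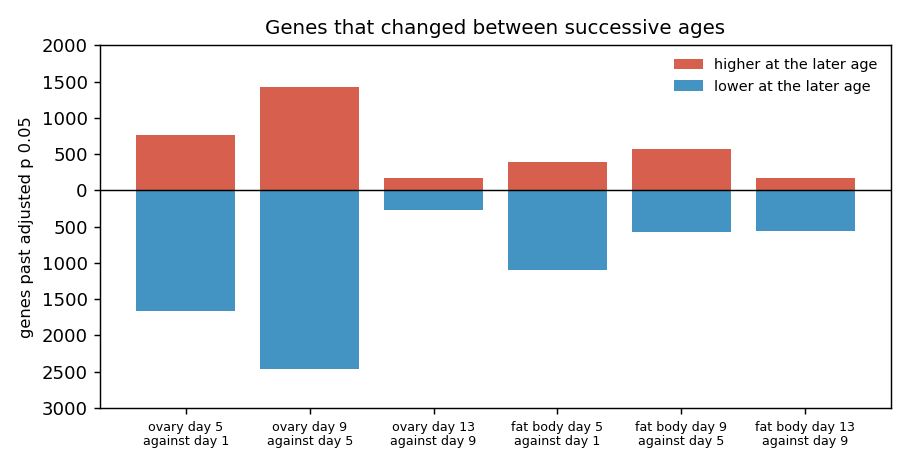
Number of genes past an adjusted p of 0.05 in each age step of each tissue, with genes higher at the later age drawn above 0 and lower ones below. The step from day 5 to day 9 in the ovary holds the most, 1419 higher and 2462 lower.

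Between day 1 and day 5 the ovary gained transcripts of oskar, of the putative vitellogenin receptor and of enzymes of steroid synthesis. Maternal effect protein oskar (MSTRG.1212), which assembles the germ plasm, rose from 2.231 ± 0.566 to 38.67 ± 5.84 FPKM (3.62 ± 0.19). The putative vitellogenin receptor (MSTRG.8753), which brings yolk precursors into the oocyte, rose from 14.15 ± 6.41 to 177.5 ± 25.6 FPKM (3.62 ± 0.45). CYP307A1-like (MSTRG.603) and CYP315A1 (MSTRG.1266), enzymes of ecdysteroid synthesis, rose by 4.12 ± 0.20 and 2.02 ± 0.25. Endochitinase (MSTRG.6083, -7.09 ± 0.39) and a phosphoenolpyruvate carboxykinase (MSTRG.1223, -7.05 ± 0.78), an enzyme of glucose synthesis, fell, the first from 328.9 ± 219 to 1.149 ± 0.369 FPKM.

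Of 9 yolk proteins 4 rose and 1 fell. Vitellogenin-1-like precursor (MSTRG.3415) rose to 422.0 ± 95.8 FPKM (2.91 ± 0.23) and vitellogenin-2-like (MSTRG.3414) to 163.0 ± 16.1 FPKM (1.96 ± 0.15), and vitellogenin-3-like MSTRG.3977 fell by 2.31. Camera gave the list an adjusted p of 0.0204, and an adjusted p = 0.317 with an estimated correlation. The benign gonial cell neoplasm protein (MSTRG.6504), which restrains germline divisions, fell from 8.685 ± 1.26 to 3.846 ± 0.665 FPKM. Of 19 germline genes 5 rose, with bicaudal C (MSTRG.10767) at 2.36 ± 0.37, and 2 fell (adjusted p 0.0278; adjusted p = 0.459 with an estimated correlation). Of 33 cell cycle genes 8 rose, with geminin (MSTRG.5021) at 1.08 ± 0.18, and 2 fell (adjusted p 0.0107; adjusted p = 0.459 with an estimated correlation). Of 7 ecdysteroid synthesis genes 4 rose and 2 fell, 1 of the latter being ecdysone 20-monooxygenase (MSTRG.5747, -1.90 ± 0.19), which makes the active hormone (adjusted p 0.0204; adjusted p = 0.317 with an estimated correlation). Ecdysone-induced protein 74EF (MSTRG.5256) fell by 2.11. The chorion and vitelline membrane list had 4 of 11 higher (adjusted p 0.0107; adjusted p = 0.323 with an estimated correlation). Eggshell peroxidase and cross-linking had 6 of 20 higher and 2 lower (adjusted p 0.0204; adjusted p = 0.459 with an estimated correlation). They include products of families that also act in cuticle, such as a yellow-like protein (MSTRG.8907) from 18.81 ± 10.1 to 324.3 ± 30.7 FPKM and laccase-1 (MSTRG.5987) at 2.49 ± 0.33. Under quantile normalization the calls of the yolk, germline and ecdysteroid synthesis lists ended, at an adjusted p of 0.0623, 0.101 and 0.118, against 0.0397, 0.0397 and 0.0457 under median-of-ratios scaling.

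The insulin-like peptide receptor (MSTRG.5296, 1.98 ± 0.26), fatty acid synthase (MSTRG.749, 1.19 ± 0.19) and an acyl-CoA desaturase (MSTRG.1993, 2.42 ± 0.37), which act in nutrient sensing and lipid synthesis, rose. So did CD109 antigen-like (MSTRG.9917, 1.45 ± 0.22), perlucin-like MSTRG.5118 (6.79 ± 0.66) and the cuticle proteins 8 (MSTRG.2469, 3.20 ± 0.31) and 16.8 (MSTRG.4089, 2.21 ± 0.37). Of 95 detoxification genes 30 fell and 7 rose, with glutathione S-transferase theta-1 (MSTRG.999, -2.34 ± 0.20), cytochrome P450 4g15 (MSTRG.4498, -2.42 ± 0.21) and P450 6d4 (MSTRG.5831, -1.56 ± 0.13) among those that fell (adjusted p 0.0107; adjusted p = 0.323 with an estimated correlation). Other lists with named members did not pass (adjusted p from 0.238 to 0.84). Higher and lower members numbered 2 and 1 of 13 for yolk uptake and endocytosis, 5 and 8 of 33 for storage and lipid, and 2 and 1 of 15 for insulin and TOR. They numbered 4 and 6 of 31 for immune genes, 4 and 1 of 42 for cuticle, 3 and 2 of 18 for ecdysone response and 3 and 16 of 47 for sugar and energy metabolism. Muscle markers had 7 of 32 higher and 2 lower (adjusted p 0.0586), and the sarcoplasmic calcium-binding protein (MSTRG.3875) fell by 2.74. Counted as higher and lower, adjusted over the list alone, were 4 and 1 yolk, 7 and 2 germline, 9 and 2 cell cycle and 4 and 2 ecdysteroid synthesis genes. The same counts were 6 and 0 for chorion, 8 and 2 for eggshell cross-linking, 7 and 36 for detoxification and 7 and 2 for muscle. In the lists that did not pass they were 2 and 1 for yolk uptake, 7 and 9 for storage and lipid, 2 and 2 for insulin and TOR, 5 and 6 for immune genes, 3 and 1 for cuticle, 3 and 3 for ecdysone response and 6 and 17 for sugar and energy.

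The test called 2426 genes, 758 higher and 1668 lower at day 5. The median of all genes was -0.10 as deposited and 0.01 after quantile normalization, and the percentage higher went from 31.2% to 42.7% under median-of-ratios scaling and 49.3% under quantile normalization. Without ovary day 5 replicate 1 it called 1599 genes, without ovary day 5 replicate 2 1189, from only the groups compared 359, and with a 2-fold threshold 1221.

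Between day 5 and day 9 the ovary gained structural transcripts of the eggshell together with those of some vitellogenins, while other vitellogenins fell. Chorion protein S36 (MSTRG.3241) rose from 2.334 ± 1.11 to 2313 ± 1240 FPKM (9.37 ± 1.03), S38 (MSTRG.3240) by 9.27 ± 0.75 and S16 (MSTRG.3904) by 9.32 ± 1.78. Vitelline membrane protein Vm26Aa-like (MSTRG.2241), of the inner eggshell layer, rose from 4.34 ± 0.918 to 1909 ± 384 FPKM (8.48 ± 0.38), and a product named skin secretory protein xP2-like (MSTRG.2533) rose by 8.85 ± 0.41. Vitellogenin-1-like precursor (MSTRG.3415) reached 7382 ± 625 FPKM (4.14 ± 0.23), vitellogenin-2-like (MSTRG.3414) 6869 ± 871 FPKM (5.39 ± 0.15) and vitellogenin-1-like MSTRG.10714 3723 ± 501 FPKM (7.08 ± 0.34). In the same step a yellow-like pair (MSTRG.8907, -5.93 ± 0.53; MSTRG.8906, -5.63 ± 0.42) and a peroxidase (MSTRG.896, -5.24 ± 0.31) fell.

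**Figure D2:**
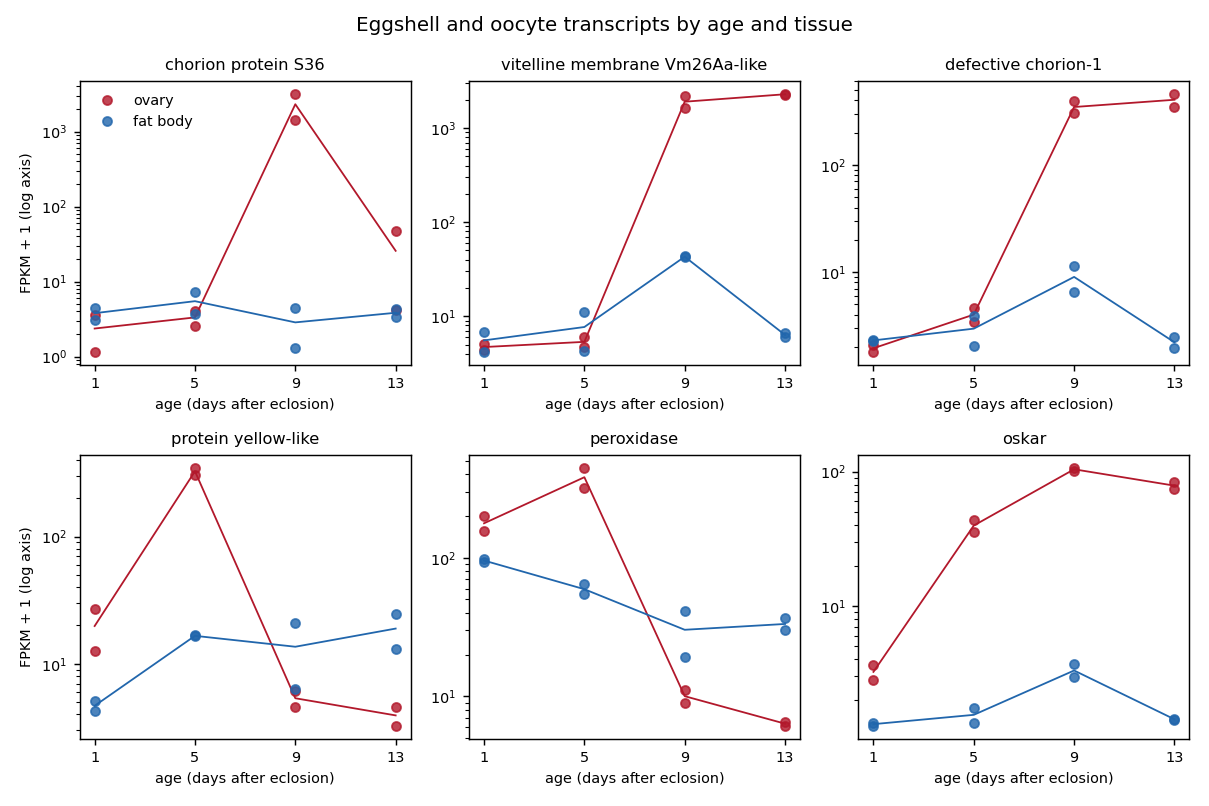
Level of 6 transcripts (FPKM plus 1, log axis) against age, with a point per library, a line through the group means, red for ovary and blue for fat body. In the ovary the yellow-like protein and the peroxidase peak at day 5, at 324.3 and 380.3 FPKM, and chorion protein S36 at day 9, at 2313 FPKM.

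Of 11 chorion and vitelline membrane genes 7 rose and 2 fell, with defective chorion-1 (MSTRG.6291) at 6.44 ± 0.34 (adjusted p 0.00345; adjusted p = 0.453 with an estimated correlation). Eggshell peroxidase and cross-linking genes had 10 of 20 lower and 2 higher (adjusted p 0.105). Of 9 yolk proteins 4 rose and 3 fell, and the fallen ones include vitellogenin-1-like MSTRG.3980, from 2222 ± 214 to 31.63 ± 2.81 FPKM (-6.09 ± 0.36), and MSTRG.3979 (-6.18 ± 1.14). The median fold change of that list was -1.56 and its mean 0.15, and camera placed it upward with an adjusted p of 0.411. Of 33 cell cycle genes 12 rose and 0 fell, with aurora borealis (MSTRG.2091, 1.69 ± 0.16), kinase Aurora-2 (MSTRG.3703, 1.62 ± 0.21) and the M-phase inducer phosphatase (MSTRG.8854, 1.86 ± 0.24), regulators of cell division (adjusted p 0.000304; adjusted p = 0.453 with an estimated correlation). Of 7 ecdysteroid synthesis genes 5 rose and 0 fell, with CYP307A1-like (MSTRG.603, 1.83 ± 0.20), CYP315A1 (MSTRG.1266, 2.24 ± 0.25) and CYP306A1 (MSTRG.4969, 2.51 ± 0.30). Camera gave the list an adjusted p of 0.000304, and an adjusted p = 0.0678 with an estimated correlation.

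Juvenile hormone epoxide hydrolase 1-like (MSTRG.9415) rose from 57.74 ± 1.18 to 507.7 ± 10.8 FPKM (3.11 ± 0.23) and hydrolase 2 (MSTRG.9412) by 1.61 ± 0.31, and Krueppel homolog 1 (MSTRG.1353), a transcription factor induced by juvenile hormone, fell by 1.47. Oskar (MSTRG.1212, 1.40 ± 0.19), its translational repressor cup (MSTRG.2454, 1.11 ± 0.14), serine protease nudel (MSTRG.6720, 4.87 ± 0.26), which acts in the axis of the embryo, and the maternal cell-cycle regulator plutonium (MSTRG.4116, 2.77 ± 0.20) rose. The insulin-like peptide receptor (MSTRG.5296) rose by 1.33 ± 0.26. Diacylglycerol O-acyltransferase 1 (MSTRG.9605, 2.16 ± 0.12) and lipid storage droplets surface-binding protein 2 (MSTRG.2275, 2.24 ± 0.22), which store neutral lipid, rose, as did maltase 2-like (MSTRG.8324, 3.53 ± 0.19), a sugar-cleaving enzyme held in the gut list. In the small RNA machinery exportin-5 (MSTRG.10548) rose by 1.06 ± 0.22 and an endoribonuclease Dicer (MSTRG.4783) fell by 1.39, with 3 of 9 genes of the list higher and 2 lower. Phenoloxidase 2 (MSTRG.1320, -3.30 ± 0.25) and heat shock protein beta-1 (MSTRG.7970, -2.51 ± 0.16) fell. Other lists with named members did not pass (adjusted p from 0.0567 to 0.919), and several had more members lower than higher. Higher and lower members numbered 4 and 12 of 33 for storage and lipid, with a median of -0.46, and 5 and 8 of 38 for gut. They numbered 5 and 7 of 29 for embryo patterning, 5 and 2 of 19 for germline, 3 and 1 of 6 for juvenile hormone and 6 and 1 of 15 for insulin and TOR. For immune genes they were 1 and 11 of 31 and for heat shock 2 and 3 of 16. Insulin and TOR, at an adjusted p of 0.0567, passed under median-of-ratios scaling at 0.0371, and had 0.0678 under quantile normalization and 0.558 with an estimated correlation. Muscle markers fell in this step, 21 of 32 with 2 higher, as in troponin I-b1 (MSTRG.5041), from 335.5 ± 14.2 to 45.49 ± 0.565 FPKM (adjusted p 0.000192; adjusted p = 0.487 with an estimated correlation). Members higher and lower, adjusted over the list alone, numbered 7 and 3 for chorion, 3 and 10 for eggshell cross-linking and 4 and 4 for yolk proteins. They numbered 12 and 0 for cell cycle, 5 and 0 for ecdysteroid synthesis, 3 and 2 for small RNA machinery and 2 and 21 for muscle. For the lists that did not pass they numbered 5 and 13 for storage and lipid, 5 and 8 for gut, 5 and 7 for embryo patterning, 5 and 2 for germline, 4 and 1 for juvenile hormone, 6 and 1 for insulin and TOR, 1 and 12 for immune genes and 1 and 3 for heat shock.

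The test called 3881 genes, 1419 higher and 2462 lower at day 9. The median of all genes was -0.15 as deposited and 0.02 and 0.01 under median-of-ratios scaling and quantile normalization, and the percentage higher went from 36.6% to 53.7% and 49.8%. With a 2-fold threshold 2377 genes passed.

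Between day 9 and day 13 fewer genes passed in the ovary, with 4 of 11 chorion genes and 2 of 9 yolk proteins lower, the latter in calls that depended on the scaling and on single libraries. Chorion protein S36 (MSTRG.3241) fell from 2313 ± 1240 to 24.74 ± 30.5 FPKM (-7.26 ± 1.03). Vitellogenin-2-like (MSTRG.3414) fell from 6869 ± 871 to 3372 ± 398 FPKM (-1.03 ± 0.15) and vitellogenin-1-like precursor (MSTRG.3415) from 7382 ± 625 to 3466 ± 320 FPKM (-1.09 ± 0.23). Exonuclease 1 (MSTRG.3520), a DNA repair enzyme, rose from 0.3658 ± 0.0814 to 27.86 ± 0.356 FPKM (4.40 ± 0.44), and senecionine N-oxygenase-like (MSTRG.9114) rose by 3.44 ± 0.36.

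Of 9 yolk proteins 2 fell and 0 rose (adjusted p 0.000122; adjusted p = 0.0845 with an estimated correlation). The calls of both depended on single libraries and on the scaling, with an adjusted p from 0.00532 to 0.291 over the alternatives for MSTRG.3414 and from 0.022 to 0.497 for MSTRG.3415. For MSTRG.3414 the change was -0.36 with an adjusted p of 0.291 under quantile normalization, -0.90 and 0.0522 without ovary day 9 replicate 1, and -0.90 and 0.0504 without ovary day 13 replicate 2. For MSTRG.3415 the adjusted p was 0.497 under quantile normalization, 0.169 and 0.0804 without ovary day 9 replicates 1 and 2, and 0.0931 and 0.161 without ovary day 13 replicates 1 and 2, with a change of -0.31 under quantile normalization. Of 33 cell cycle genes 2 rose and 0 fell, and camera placed the list upward with an adjusted p of 2.3e-05 and an adjusted p = 0.265 with an estimated correlation. Of 11 chorion genes 4 fell, while the list's median fold change was 0.05, its mean -1.56 and camera's direction down (adjusted p 0.0337; adjusted p = 0.468 with an estimated correlation). That call held under median-of-ratios scaling (adjusted p 0.0366) and ended under quantile normalization (adjusted p 0.132). Camera also placed eggshell peroxidase and cross-linking (0 of 20 higher, 4 lower; adjusted p 0.00668; adjusted p = 0.439 with an estimated correlation) and immune genes (1 of 31 higher, 0 lower; adjusted p 0.00521; adjusted p = 0.468 with an estimated correlation) down. It placed cytosolic ribosomal proteins down as well (adjusted p 0.0003; adjusted p = 0.619 with an estimated correlation), with a median of -0.19 that turned to 0.07 under quantile normalization, where the call ended (adjusted p 0.879, against 0.000419 under median-of-ratios scaling). Ecdysone response, with 0 of 18 higher and 3 lower, and detoxification, with 1 of 95 higher and 1 lower, passed downward at an adjusted p of 0.0322 each. Both held under median-of-ratios scaling (adjusted p 0.0366 and 0.0441) and ended under quantile normalization (adjusted p 0.262 and 0.322) and with an estimated correlation (adjusted p 0.619 and 0.439). The proteasome, with 0 of 19 higher and 0 lower, passed upward (adjusted p 0.0344; adjusted p = 0.619 with an estimated correlation), and had 0.062 under median-of-ratios scaling and 0.0336 under quantile normalization. Cuticle protein 8 (MSTRG.2469, -2.15 ± 0.31), a chymotrypsin-like protease CTRL-1 (MSTRG.10276, -1.83 ± 0.26) and a probable kinase clkA (MSTRG.891, -4.42 ± 0.29) fell, while the cuticle list had 2 of 42 lower and 0 higher (adjusted p 0.676) and the gut list 3 of 38 lower and 0 higher (adjusted p 0.257). Muscle markers fell with the yolk and chorion genes, 6 of 32 with 1 higher, as in troponin I-b1 (MSTRG.5041, -1.26 ± 0.19), at an adjusted p of 2.3e-05 and an adjusted p = 0.439 with an estimated correlation. Adjusted over the list alone, higher and lower members numbered 0 and 5 for yolk proteins, 4 and 0 for cell cycle, 0 and 5 for chorion, 0 and 4 for eggshell cross-linking, 1 and 6 for immune genes, 0 and 0 for ribosomal proteins, 0 and 2 for cuticle, 0 and 4 for gut and 1 and 12 for muscle. They numbered 0 and 3 for ecdysone response and 0 and 0 for detoxification and the proteasome.

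The test called 431 genes, 166 higher and 265 lower at day 13, and with a 2-fold threshold 222. It called 165 and 207 without ovary day 9 replicates 1 and 2, 155 and 157 without ovary day 13 replicates 1 and 2, and 282 and 281 without fat body day 5 replicates 1 and 2. It called 261 under quantile normalization and 4 from only the groups compared.

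Between day 1 and day 5 the fat body gained transcripts of 2 vitellogenins and of 2 proteins of lipid transport. Vitellogenin-1-like precursor (MSTRG.3415) rose from 70.4 ± 7.2 to 1933 ± 304 FPKM (4.75 ± 0.23) and vitellogenin-2-like (MSTRG.3414) from 56.14 ± 7.7 to 987.3 ± 37.4 FPKM (4.12 ± 0.15). Apolipophorins (MSTRG.506), the lipid carrier of the hemolymph, rose from 229.2 ± 93.6 to 1090 ± 54.8 FPKM (2.31 ± 0.24), and the microsomal triglyceride transfer protein (MSTRG.4400), which loads such carriers, by 1.14 ± 0.14. A-kinase anchor protein 14 (MSTRG.3524) fell from 1682 ± 251 to 11.57 ± 2.44 FPKM (-7.07 ± 0.68), the phosphoenolpyruvate carboxykinase MSTRG.1223 by 5.86 and endochitinase (MSTRG.6083) by 4.80.

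**Figure D3:**
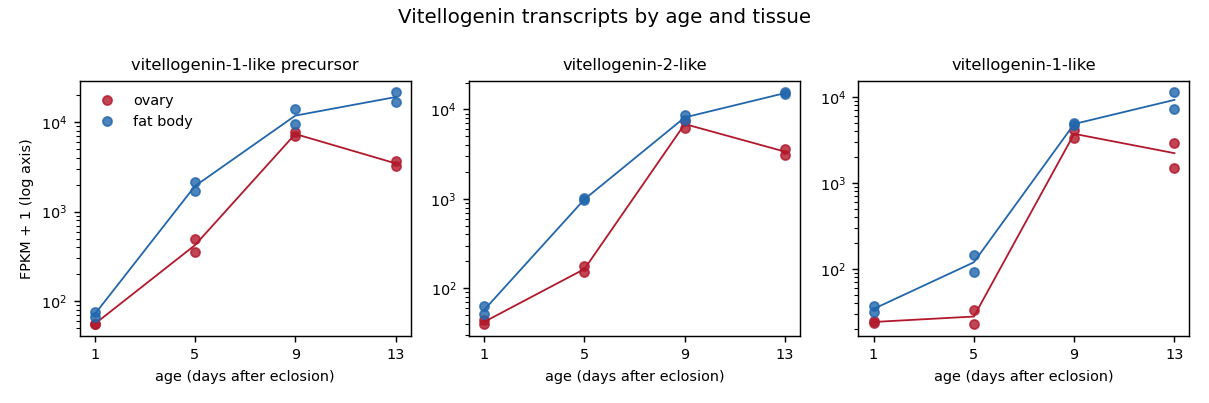
Level of 3 vitellogenin transcripts (FPKM plus 1, log axis) against age, with a point per library, a line through the group means, red for ovary and blue for fat body. In the fat body the vitellogenin-2-like transcript goes from 56.14 FPKM at day 1 to 15260 FPKM at day 13, and in the ovary it peaks at day 9, at 6869 FPKM.

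Of 9 yolk proteins 3 rose and 1 fell, the latter vitellogenin-3-like MSTRG.3977 (-1.44 ± 0.18), at an adjusted p of 0.0202 and an adjusted p = 0.377 with an estimated correlation. The call ended under both other scalings, with an adjusted p of 0.13 under median-of-ratios scaling and 0.0768 under quantile normalization. Storage and lipid genes had 5 of 33 higher and 2 lower and did not pass (adjusted p 0.276), with a median of -0.16 and a mean of -0.01 while camera's direction was up. The chorion list passed upward with 1 of 11 higher (adjusted p 0.0199; adjusted p = 0.519 with an estimated correlation), and had 0.057 under median-of-ratios scaling and 0.0383 under quantile normalization. Ribosomal proteins, with 0 of 58 higher and 0 lower, did not pass (adjusted p 0.31; adjusted p = 0.936 with an estimated correlation), and had 0.797 and, downward, 0.000196 under those scalings. Of 19 proteasome genes 11 fell and 0 rose, with regulatory subunits 11 (MSTRG.7669, -0.93 ± 0.09), 12 (MSTRG.5836, -1.31 ± 0.13) and 14 (MSTRG.4565, -1.23 ± 0.15). The list test gave an adjusted p of 3.26e-06, and an adjusted p = 0.519 with an estimated correlation. Among immune genes, 4 of 31 rose and 2 fell, with CD109 antigen (MSTRG.9915, 1.13 ± 0.14), CD109 antigen-like (MSTRG.9917, 1.71 ± 0.22) and gram-negative bacteria-binding protein 1 (MSTRG.3066, 1.77 ± 0.21) among the risen (adjusted p 0.0959). Of 42 cuticle genes 8 rose and 11 fell (adjusted p 0.251), with pro-resilin-like (MSTRG.5028) from 33.44 ± 27.0 to 1110 ± 297 FPKM (5.25 ± 0.60). Larval cuticle protein 8-like (MSTRG.11142, -2.83 ± 0.17) and cuticle protein 63 (MSTRG.4911, -2.78 ± 0.24) fell. Of 95 detoxification genes 4 rose and 17 fell (adjusted p 0.362), with venom carboxylesterase-6 (MSTRG.1030) at 3.83 ± 0.33 and P450 12e1 (MSTRG.9844) at -1.76 ± 0.17. The hormone receptor FTZ-F1-like (MSTRG.1549, 1.48 ± 0.21) rose, and juvenile hormone epoxide hydrolase 2-like (MSTRG.9416, -1.18 ± 0.16) and trehalose transporter Tret1-2 homolog MSTRG.4057 (-2.41 ± 0.23) fell. Their lists did not pass, with 1 of 18 ecdysone response genes higher and 3 lower (adjusted p 0.894), 1 of 6 juvenile hormone genes higher and 1 lower (adjusted p 0.856) and 3 of 47 sugar and energy genes higher and 7 lower (adjusted p 0.894). Muscle markers rose in this step, 15 of 32 with 1 lower, as in paramyosin (MSTRG.3905, 1.61 ± 0.24) and troponin I-b1 (MSTRG.5041, 1.18 ± 0.19). The list test gave an adjusted p of 8.97e-09, and an adjusted p = 0.377 with an estimated correlation. Adjusted over the list alone, higher and lower members numbered 3 and 1 for yolk proteins, 0 and 14 for the proteasome, 4 and 2 for immune genes, 14 and 13 for cuticle, 5 and 23 for detoxification and 18 and 3 for muscle. They numbered 7 and 5 for storage and lipid, 1 and 3 for ecdysone response, 1 and 2 for juvenile hormone, 3 and 7 for sugar and energy, 1 and 0 for chorion and 0 and 0 for ribosomal proteins.

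The test called 1484 genes, 388 higher and 1096 lower at day 5. The median of all genes was -0.11 as deposited and 0.01 and -0.01 under median-of-ratios scaling and quantile normalization, and the percentage higher went from 26.1% to 50.1% and 47.4%. Without fat body day 1 replicate 1 it called 758 genes, without fat body day 5 replicates 1 and 2 707 and 612, from only the groups compared 137, and with a 2-fold threshold 731.

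Between day 5 and day 9 some vitellogenin and immune transcripts rose in the fat body libraries and some cuticle transcripts fell. With an estimated correlation the calls of the yolk and immune lists ended and that of the cuticle list held. Vitellogenin-1-like MSTRG.10714 rose from 118.4 ± 37.0 to 4848 ± 157 FPKM (5.38 ± 0.34), vitellogenin-2-like (MSTRG.3414) by 3.04 ± 0.15 and vitellogenin-1-like precursor (MSTRG.3415) by 2.59 ± 0.23. Peptidoglycan-recognition protein SB1-like (MSTRG.10314), which acts on bacterial cell walls, rose from 17.15 ± 0.999 to 223.9 ± 27.4 FPKM (3.63 ± 0.57). Larval cuticle protein LCP-30 (MSTRG.2130) fell from 98.93 ± 46.5 to 1.815 ± 0.996 FPKM (-5.11 ± 0.40), cuticle protein 8 (MSTRG.3006) by 4.51 and endocuticle structural glycoprotein ABD-4 (MSTRG.2131) by 4.38.

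Of 42 cuticle genes 19 fell and 1 rose, with cuticle protein 16.5 (MSTRG.6578) at -3.57 ± 0.22, and camera called the list at an adjusted p of 4.97e-11 and at 0.0182 with the estimated correlation. Of 31 immune genes 8 rose and 0 fell, with CD109 antigen (MSTRG.9915) at 1.31 ± 0.14 (adjusted p 9.81e-07; adjusted p = 0.125 with an estimated correlation). Of 9 yolk proteins 3 rose and 0 fell (adjusted p 0.00487; adjusted p = 0.125 with an estimated correlation). Of 95 detoxification genes 13 rose and 3 fell, with UDP-glucuronosyltransferase 2B33 (MSTRG.4934, 3.75 ± 0.41) and venom carboxylesterase-6 (MSTRG.1030, 3.05 ± 0.33). Camera gave the list an adjusted p of 0.00147, and an adjusted p = 0.125 with an estimated correlation. Of 29 maternal embryo patterning genes 9 rose and 1 fell, called at 0.000642 and at 0.0288 with the estimated correlation. Those that rose include easter-like MSTRG.4311 (1.48 ± 0.18) and snake-like MSTRG.8880 (2.23 ± 0.32), serine proteases of a kind that also acts in hemolymph. Of 38 gut markers 7 rose and 0 fell, with a chymotrypsin inhibitor-like product (MSTRG.4707, 2.59 ± 0.21), which is an inhibitor and not a digestive enzyme (adjusted p 0.000241; adjusted p = 0.199 with an estimated correlation). Acetyl-CoA carboxylase (MSTRG.8122, -1.15 ± 0.20) and fatty acid synthase (MSTRG.749, -1.11 ± 0.19), of fatty acid synthesis, glycogen phosphorylase (MSTRG.2622, -1.19 ± 0.15) and a succinate dehydrogenase subunit (MSTRG.7621, -2.33 ± 0.24) fell. Among storage and lipid genes 1 of 33 was higher and 4 lower (adjusted p 0.147), and in sugar and energy 5 of 47 were higher and 4 lower (adjusted p 0.0728). Oxidative phosphorylation had 0 of 45 higher and 1 lower (adjusted p 0.361). Under quantile normalization the first and last of these lists passed downward (adjusted p 0.0326 and 0.00803), but not under median-of-ratios scaling (adjusted p 0.246 and 0.699) or with an estimated correlation (adjusted p 0.753 and 0.843). Muscle markers, with 0 of 32 higher and 0 lower, had an adjusted p of 0.253 as deposited, 0.314 under median-of-ratios scaling, 0.0276 downward under quantile normalization and 0.843 with an estimated correlation. Ribosomal proteins, with 0 of 58 higher and 0 lower, passed downward (adjusted p 0.0226; adjusted p = 0.843 with an estimated correlation), and had 0.145 and 1.13e-10 under those scalings. Trehalose transporter Tret1-2 homolog MSTRG.4057 (2.91 ± 0.23), odorant-binding protein 99a-like (MSTRG.9806, 3.79 ± 0.65) and tenascin-R-like (MSTRG.6616, 4.45 ± 0.50) rose.

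Transcripts of the ovary rose in the fat body in this step as well. Vitelline membrane protein Vm26Aa-like (MSTRG.2241, 2.64 ± 0.38), chorion peroxidase MSTRG.6306 (2.10 ± 0.26), oskar (MSTRG.1212, 1.10 ± 0.19) and juvenile hormone epoxide hydrolase 1-like (MSTRG.9415, 1.75 ± 0.23) rose. With an ovarian share subtracted from the fat body libraries, an alternative chosen after the data were seen, the first 3 calls ended. The changes were then 1.04 ± 0.50, 0.65 ± 0.28 and 0.00 ± 0.16 (adjusted p 0.222, 0.177 and 1, each the highest over the alternatives). The lists had 3 of 11 chorion, 3 of 19 germline, 2 of 33 cell cycle and 3 of 7 ecdysteroid synthesis genes higher and 0 lower in each. Of these the chorion, germline and cell cycle lists did not pass (adjusted p 0.087, 0.0957 and 0.0879). Cell cycle had 0.0883 under median-of-ratios scaling, 0.0166 under quantile normalization and 0.512 with an estimated correlation. Camera gave an adjusted p of 0.0226 for ecdysteroid synthesis, and an adjusted p = 0.125 with an estimated correlation. Over 79 ovary-specific genes, chosen after the data were seen, the median level was 3.4% and 2.06% of that of the ovary at day 9 in the fat body libraries of day 9, against 0.33% and 0.8% in those of day 5. The higher and lower members, adjusted over the list alone, were 1 and 22 for cuticle, 14 and 1 for immune genes, 3 and 0 for yolk proteins and 18 and 4 for detoxification. They were 13 and 1 for embryo patterning, 11 and 0 for gut, 4 and 1 for chorion, 4 and 0 for germline, 2 and 0 for cell cycle, 3 and 0 for ecdysteroid synthesis, 1 and 4 for storage and lipid, 7 and 4 for sugar and energy, 0 and 1 for oxidative phosphorylation and 0 and 0 for muscle and ribosomal proteins.

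The test called 1137 genes, 565 higher and 572 lower at day 9, and with a 2-fold threshold 741. Without fat body day 5 replicates 1 and 2 it called 563 and 746 genes, without fat body day 9 replicate 2 699, and from only the groups compared 566.

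**Figure D4:**
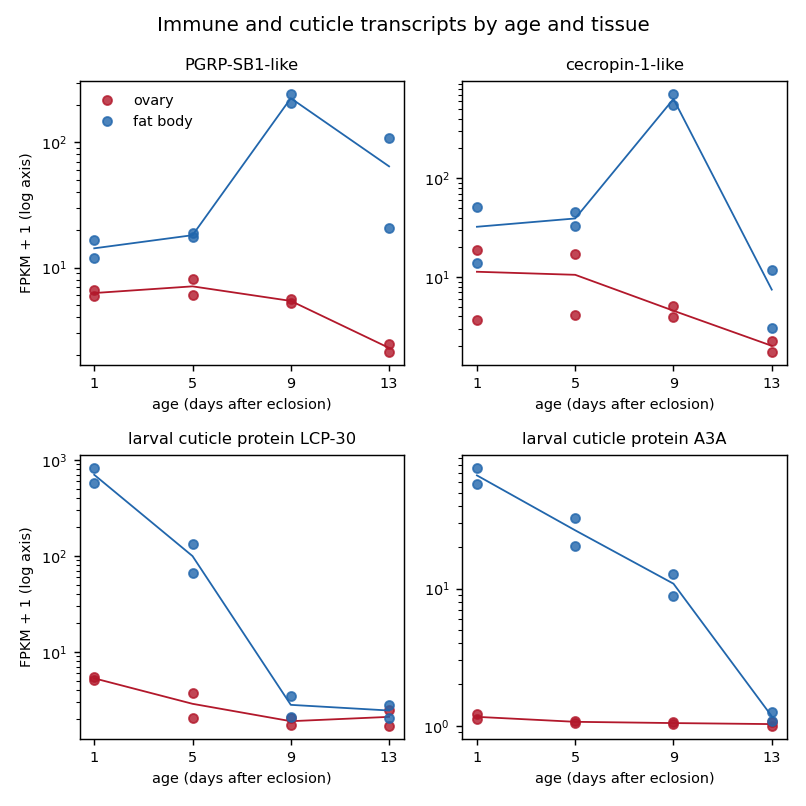
Level of 2 immune and 2 cuticle transcripts (FPKM plus 1, log axis) against age, with a point per library, a line through the group means, red for ovary and blue for fat body. In the fat body cecropin-1-like peaks at day 9, at 632.6 FPKM, and larval cuticle protein LCP-30 goes from 98.93 FPKM at day 5 to 1.815 FPKM at day 9.

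Between day 9 and day 13 some antimicrobial, cuticle and muscle transcripts fell in the fat body libraries. The calls of these lists ended with an estimated correlation. The step shares day 9 libraries with the one before, so their immune state was not separated from age. The source cells of the cuticle and muscle transcripts were not tested. Cecropin-1-like MSTRG.10389, an antimicrobial peptide, fell from 632.6 ± 116 to 6.474 ± 6.2 FPKM (-6.70 ± 0.94) and cecropin-1-like MSTRG.10390 by 3.92, while lysozyme (MSTRG.5389), which cleaves bacterial walls, rose by 1.94 ± 0.27. Larval cuticle protein A3A (MSTRG.10119, -3.19 ± 0.25), pupal cuticle protein Edg-78E-like (MSTRG.6707, -3.33 ± 0.32) and G1A-like (MSTRG.4912, -2.81 ± 0.32) fell. Vitellogenin-2-like (MSTRG.3414) went from 8148 ± 781 to 15260 ± 358 FPKM (0.91 ± 0.15, adjusted p 0.0068), a rise that turned to -0.32 under quantile normalization (adjusted p 0.261, in a range from 0.00386 to 0.261 over the alternatives). The tyrosine-degrading enzyme 4-hydroxyphenylpyruvate dioxygenase (MSTRG.4833, 2.41 ± 0.28), peroxiredoxin-6-like (MSTRG.8360, 2.16 ± 0.27) and homocysteine S-methyltransferase 1 (MSTRG.3516, from 67.87 ± 6.07 to 274.3 ± 29.7 FPKM) rose.

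Of 42 cuticle genes 14 fell and 1 rose (adjusted p 4.23e-07; adjusted p = 0.0701 with an estimated correlation). Of 31 immune genes 8 fell and 1 rose (adjusted p 0.00659; adjusted p = 0.324 with an estimated correlation). Of 33 storage and lipid genes 3 rose and 1 fell, with the larval serum protein 2 (MSTRG.5581, 1.47 ± 0.13), a storage protein, and a fatty acid elongase (MSTRG.9793, 1.63 ± 0.20). The list test gave an adjusted p of 0.0237, and an adjusted p = 0.364 with an estimated correlation. L-lactate dehydrogenase (MSTRG.10109, -1.01 ± 0.14), trehalose transporter MSTRG.4057 (-1.45 ± 0.23), succinate dehydrogenase subunit MSTRG.7621 (-1.46 ± 0.24), UDP-glucuronosyltransferase 2B33 (MSTRG.4934, -3.28 ± 0.41) and the protease easter (MSTRG.10385, -4.56 ± 0.52) fell. In sugar and energy metabolism 6 of 47 were lower and 0 higher (adjusted p 0.108), and in detoxification 5 of 95 lower and 3 higher (adjusted p 0.795). Embryo patterning had 3 of 29 lower and 0 higher (adjusted p 0.0149; adjusted p = 0.143 with an estimated correlation). The yolk protein list had 1 of 9 higher and 0 lower (adjusted p 0.00659; adjusted p = 0.143 with an estimated correlation). Its median went from 0.65 as deposited to 0.80 under median-of-ratios scaling (adjusted p 0.0179) and 0.10 under quantile normalization, where the call ended (adjusted p 0.996). Oxidative phosphorylation had 4 of 45 lower and 0 higher (adjusted p 0.00287; adjusted p = 0.362 with an estimated correlation), a call that held under median-of-ratios scaling (adjusted p 0.0189) and ended under quantile normalization (adjusted p 0.063). Heat shock proteins had 2 of 16 higher (adjusted p 0.00753; adjusted p = 0.324 with an estimated correlation). Of 58 cytosolic ribosomal proteins 1 fell, with a median fold change of -0.47 as deposited, -0.34 under median-of-ratios scaling and -0.10 under quantile normalization (adjusted p 2.29e-06; adjusted p = 0.364 with an estimated correlation). Muscle markers fell beside the cuticle and immune genes, 7 of 32 with 0 higher, as in troponin I-b1 (MSTRG.5041, -1.26 ± 0.19), at an adjusted p of 1.6e-05 and an adjusted p = 0.324 with an estimated correlation. Gut markers had 4 of 38 lower and 1 higher, at an adjusted p of 0.0927 as deposited, 0.0415 under median-of-ratios scaling, 0.037 under quantile normalization and 0.467 with an estimated correlation. Eggshell peroxidase and cross-linking had 4 of 20 lower and 0 higher (adjusted p 0.0237; adjusted p = 0.324 with an estimated correlation). Ecdysteroid synthesis had 2 of 7 lower and 0 higher, at an adjusted p of 0.0793 as deposited, 0.052 and 0.0457 under those scalings and 0.324 with an estimated correlation.

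The ovary-type transcripts fell again in the fat body: Vm26Aa-like (MSTRG.2241, -2.77 ± 0.38), chorion peroxidase MSTRG.6306 (-2.18 ± 0.26), cyclin-B (MSTRG.8707, -2.36 ± 0.40), oskar (MSTRG.1212, -1.20 ± 0.19), bicaudal C (MSTRG.10767, -2.07 ± 0.37) and the insulin-like peptide receptor (MSTRG.5296, -1.85 ± 0.26). With the ovarian share subtracted all of these calls ended, an outcome again largely fixed by the method. The changes were then -0.86 ± 0.50, -0.59 ± 0.28, 0.29 ± 0.26 and 0.09 ± 0.16 for the first 4 (adjusted p 0.389, 0.272, 0.639 and 0.873), 0 with an adjusted p of 1 for bicaudal C and -0.15 ± 0.24 with an adjusted p of 0.855 for the receptor. These were the highest adjusted p over the alternatives. Members that fell numbered 4 of 11 for chorion (adjusted p 0.0237; adjusted p = 0.324 with an estimated correlation), 4 of 19 for germline (adjusted p 0.0525, with 0.0441 and 0.0236 under median-of-ratios scaling and quantile normalization and 0.352 with an estimated correlation) and 3 of 33 for cell cycle (adjusted p 0.00659; adjusted p = 0.324 with an estimated correlation). With p adjusted over the list alone, higher and lower members numbered 1 and 18 for cuticle, 1 and 11 for immune genes, 5 and 2 for storage and lipid and 2 and 0 for yolk proteins. They numbered 0 and 10 for oxidative phosphorylation, 2 and 0 for heat shock, 0 and 0 for ribosomal proteins, 0 and 12 for muscle, 0 and 5 for chorion, 0 and 5 for germline and 0 and 8 for cell cycle. For sugar and energy, detoxification and embryo patterning they were 2 and 11, 4 and 5, and 0 and 5, and for gut, eggshell cross-linking and ecdysteroid synthesis 1 and 5, 0 and 7, and 0 and 3.

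The test called 731 genes, 177 higher and 554 lower at day 13, and with a 2-fold threshold 435. The median of all genes was -0.07 as deposited and 0.06 after quantile normalization, and the percentage higher went from 24.2% to 39.9% under median-of-ratios scaling and 44.9% under quantile normalization. Without fat body day 9 replicates 1 and 2 it called 425 and 486 genes, without fat body day 13 replicate 1 400, and from only the groups compared 1.

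The interaction asked in which genes an age step differed between the tissues. Vitellogenins differed in both directions. Between days 1 and 5 the change of vitellogenin-2-like (MSTRG.3414) differed, ovary minus fat body, by -2.15 ± 0.21 and that of vitellogenin-1-like precursor (MSTRG.3415) by -1.85 ± 0.32 (adjusted p 0.00066 and 0.00983). In the same step vitellogenin-1-like MSTRG.3980 had the more positive change in the ovary, by 2.04 ± 0.51 (adjusted p 0.0363). That call ended with a pseudocount of 0.1 (adjusted p 0.0641), and with ovary day 1 replicate 2 or any 1 library of fat body day 1, of day 5 or of ovary days 9 and 13 left out (adjusted p from 0.0507 to 0.111). Between days 5 and 9 the ovary rose further, by 2.35 ± 0.21, 1.55 ± 0.32 and 1.70 ± 0.48 for MSTRG.3414, MSTRG.3415 and vitellogenin-1-like MSTRG.10714 (adjusted p 8.06e-05, 0.0059 and 0.0254), while MSTRG.3980 fell further there, by a difference of -5.27 ± 0.51 (adjusted p 9.64e-05). The call of MSTRG.10714 ended without ovary day 5 replicate 2, fat body day 5 replicate 1, ovary day 9 replicate 1 or either fat body library of day 9 (adjusted p from 0.0575 to 0.096), and with the ovarian share subtracted (adjusted p 0.0819). Between days 9 and 13 vitellogenin-2-like had a difference of -1.93 ± 0.21 (adjusted p 0.00198), which went to -0.04 under quantile normalization (adjusted p 0.964, the highest over the alternatives).

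Endochitinase (MSTRG.6083) fell further in the ovary from day 1 to day 5, by a difference of -2.30 ± 0.56 (adjusted p 0.0334). The call ended under median-of-ratios scaling (adjusted p 0.0616), with a pseudocount of 0.1 (adjusted p 0.0771), and with any 1 library of fat body day 1, of day 5 or of ovary days 9 and 13 left out (adjusted p from 0.0514 to 0.116). Vm26Aa-like (MSTRG.2241) and juvenile hormone epoxide hydrolase 1-like (MSTRG.9415) rose further in the ovary from day 5 to day 9, by 5.84 ± 0.54 and 1.36 ± 0.32 (adjusted p 8.09e-05 and 0.0106). In 5 genes that changed in both tissues in a step, the difference did not pass in that step. These were the phosphoenolpyruvate carboxykinase (MSTRG.1223), CD109 antigen-like (MSTRG.9917) and vitellogenin-3-like MSTRG.3977 from day 1 to day 5 (adjusted p 0.581, 0.683 and 0.0638), oskar (MSTRG.1212) from day 5 to day 9 (adjusted p 0.459) and troponin I-b1 (MSTRG.5041) from day 9 to day 13 (adjusted p 0.995). The difference of -0.87 ± 0.25 for MSTRG.3977 passed under quantile normalization (-1.57, adjusted p 0.00752), with a random block by age and number (adjusted p 0.0381) and without ovary day 5 replicate 1 (adjusted p 0.0335). That of 0.30 ± 0.27 for oskar passed with the ovarian share subtracted (1.40, adjusted p 0.00142, in a range up to 0.83 over the alternatives), which follows from what was subtracted in the fat body. In other steps these genes differed more, as oskar did from day 1 to day 5 (3.40 ± 0.27, adjusted p 0.00034). From day 5 to day 9 so did MSTRG.3977 (-1.80 ± 0.25, adjusted p 0.000666), CD109 antigen-like (-2.72 ± 0.31, adjusted p 0.000229) and troponin I-b1 (-2.49 ± 0.27, adjusted p 0.000168).

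Over all genes the change differed between the tissues in 813 genes from day 1 to day 5 (420 with the more positive log2 change in the ovary), 2687 from day 5 to day 9 (1026) and 562 from day 9 to day 13 (384). The median difference over all genes was -0.10 as deposited and 0.04 under median-of-ratios scaling for the second step, and 0.11 and 0.00 for the last. The percentage with the more positive change in the ovary was 51.7% for the first step, 38.2% for the second and 68.3% for the last. It went to 44.4%, 49.6% and 54.2% under median-of-ratios scaling and to 52.2%, 51.6% and 50.7% under quantile normalization. The first count was 291 with a pseudocount of 0.1, 151 from only the groups compared, 375 without ovary day 5 replicate 2, and 371 and 382 without fat body day 5 replicates 1 and 2. The last was 311 from only the groups compared, 259 and 318 without ovary day 9 replicates 1 and 2, 328 without fat body day 9 replicate 1, and 240 and 272 without ovary day 13 replicates 1 and 2.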

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

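The tests of ovarian carry-over, of scaling, of fat body carry-over and of immune state below were chosen after the results were seen, while the tests of the difference between tissues were planned, apart from the choice of 6 pairs of gene and step. In each age step some genes changed by different amounts in the 2 tissues, tested as an interaction: 813 from day 1 to day 5, 2687 from day 5 to day 9 and 562 from day 9 to day 13. Among the 14 pairs of gene and step named in both tissues 9 differed. The 6 other pairs, chosen after their values were seen, all differed. They were MSTRG.3980 in the first 2 steps, oskar (MSTRG.1212) in the first and MSTRG.3977, MSTRG.9917 and MSTRG.5041 in the second. The calls of MSTRG.3980 and endochitinase (MSTRG.6083) in the first step, of MSTRG.10714 in the second and of MSTRG.3414 in the last did not hold under every alternative. From day 1 to day 5 the ovary minus fat body difference of log2 changes was -2.15 for vitellogenin-2-like (MSTRG.3414), -1.85 for vitellogenin-1-like precursor (MSTRG.3415), -2.295 for endochitinase (MSTRG.6083), 2.036 for vitellogenin-1-like MSTRG.3980 and 3.40 for oskar (MSTRG.1212). From day 5 to day 9 it was 5.84 for Vm26Aa-like (MSTRG.2241), 2.345 for MSTRG.3414, 1.55 for MSTRG.3415, 1.70 for vitellogenin-1-like MSTRG.10714 and 1.36 for juvenile hormone epoxide hydrolase 1-like (MSTRG.9415), and -5.27 for MSTRG.3980, -1.80 for vitellogenin-3-like MSTRG.3977, -2.72 for CD109 antigen-like (MSTRG.9917) and -2.49 for troponin I-b1 (MSTRG.5041). From day 9 to day 13 it was -1.93 for MSTRG.3414.

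Ovary-abundant transcripts such as Vm26Aa-like (MSTRG.2241), cyclin-B (MSTRG.8707), oskar (MSTRG.1212) and vasa (MSTRG.707) were found in the fat body libraries of day 9 at 2.16%, 3.1%, 2.59% and 4.42% of their ovary level in replicate 1 and 2.23%, 2.03%, 1.88% and 4.51% in replicate 2. Vasa was not particular to day 9. Its levels there, 22.61 and 23.11 FPKM, lay above its mean over all fat body libraries, given above, but that mean places it in the fat body at other ages too. The scaling of these libraries is argued against: their mean size factor was 0.92 times that of day 5 while the ovarian share was 4.85 times. Ovarian tissue carried over at dissection may be a source, since 64.6% of 79 ovary-specific genes in replicate 2 and 86.1% in replicate 1 lay within 2-fold of the median share of 2.06% and 3.4%, against a median share of 0.33% and 0.8% at day 5, the one other age that did not enter the choice of these genes. Chorion proteins S36 (MSTRG.3241) at 0.0127% and 0.148%, S38 (MSTRG.3240) at 0.443% and 0.148% and S16 (MSTRG.3904) at 6.88% and 0.0895% lay off the median share of day 9. Expression by fat body cells at this age was not tested and stays open.

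Vitellogenin transcripts were abundant in the ovary at day 9, at 62.4%, 84.3% and 76.8% of the fat body level of that age for MSTRG.3415, MSTRG.3414 and MSTRG.10714. Fat body tissue carried into the ovary libraries is argued against as the main cause. Over 84 genes abundant in the fat body at day 9 and at most 5% of that level in the ovary at day 1, a choice that leaves out genes the ovary expressed at that age, the median share found in the ovary at day 9 was 1.4%, with quartiles of 0.87% and 1.94%, and 7 of them came near the vitellogenins, at a share that was 0.5 times the lowest vitellogenin share or more. Transcription in the ovary itself, a candidate explanation, was not tested and stays open.

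Of 31 antimicrobial and recognition genes 8 were called higher in the fat body at day 9 than at day 5. Their median step of 3.02 on the log2 scale is one over genes chosen for the step, and the median of all 31 was 0.60. Carried-over ovarian tissue is argued against: it would bring at most 4.5% of the level of any of the 8. A difference in immune state between pools of flies could be a cause, of the later fall too, and stays open. The median over the 8 genes of the largest replicate difference at another age was 1.84, but to set it against the step decides nothing, as the genes were chosen for a large step and the bound of that test was widened after its result was seen. Scaling stays open too for part of the set, as 7 of the 8 passed under both other scalings, and age was not separated from these.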

How the results depend on the processing

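The settings named ovarian share subtracted and fat body day 9 left out were chosen after seeing the data, and all others were planned. Of 5335 refits of the 201 pairs of named gene and comparison, 5216 kept direction and side of the threshold. That share was largely fixed by the choice of genes and says little about stability, because the genes given for the age steps and the tissues had been narrowed, after the data were seen, to calls that held. The call was lost without a turn in 104 (59 from only the groups compared, 7 with the ovarian share subtracted, 3 under quantile normalization, 2 with a pseudocount of 0.1, 1 under median-of-ratios scaling and 32 with a library left out), 4 gained it and 11 turned. Among the 7, bicaudal C (MSTRG.10767) in the fat body from day 9 to day 13 came to 0 and so had no direction left. With the ovarian share subtracted the change of oskar (MSTRG.1212) in the fat body was 0.00 from day 5 to day 9 and 0.09 from day 9 to day 13, and that of cyclin-B (MSTRG.8707) 0.29 from day 9 to day 13, which follows from what was subtracted. Under quantile normalization vitellogenin-2-like (MSTRG.3414) in the fat body from day 9 to day 13 was -0.32. That method gives every library the same set of values, which bounds the change of transcripts near the top. The highest level in a fat body library was 14189.9 and 9485.7 FPKM at day 9 and 21512.8 and 23784.3 FPKM at day 13. Levels of this vitellogenin, given above, were of the same order. The bound also applies to the vitellogenins of the last ovary step. How far it made these changes was not tested. The other turns were in differences between the tissues that had not passed. From day 1 to day 5 that of CD109 antigen-like (MSTRG.9917) was 0.20 under quantile normalization and -0.57 to 0.05 with 1 library left out, and that of the phosphoenolpyruvate carboxykinase (MSTRG.1223) -2.66 to 0.29. From day 5 to day 9 that of oskar was -0.53 with a pseudocount of 0.1, and from day 9 to day 13 that of troponin I-b1 (MSTRG.5041) ran from -0.12 to 0.11 with 1 library left out; the cause was not tested.

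Counts that left a range of 1.5 times are given here by setting, and the cause was not tested where none is named. From only the groups compared, with fewer libraries to estimate the spread, they were 359, 4 and 566 for ovary day 5 against day 1, ovary day 13 against day 9 and fat body day 9 against day 5, 137 and 1 for the first and last fat body steps, and 151 and 311 for the first and last difference between tissues. With a 2-fold threshold, which removes small changes by construction, they were 1221, 2377 and 222 for the ovary steps, 731, 741 and 435 for the fat body steps and 5337 between the tissues. The first difference between tissues gave 291 with a pseudocount of 0.1, the last 369 with the ovarian share subtracted, and the last ovary step 261 under quantile normalization. With the estimated correlation in place of the preset one, 6 of 60 list calls passed. Under median-of-ratios scaling 55 of the 60 calls were kept, 5 were lost and 5 others gained, and under quantile normalization 48 were kept, 12 lost and 12 gained.

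With 1 library left out, where the lone library of the group is taken to vary like the others, counts ran from 1189 to 2544, 2807 to 4126 and 155 to 458 for the ovary steps, 612 to 1630, 563 to 1257 and 400 to 816 for the fat body steps, 8245 to 8485 between the tissues, and 371 to 1059, 1933 to 2949 and 240 to 593 for the differences. The other alternatives kept every count within 1.5 times. Without fat body day 9, 8011 genes differed between the tissues. A replicate block gave 2234 genes for the first ovary step, 8381 between the tissues and 712, 2537 and 432 for the differences. A random block by age and number gave 2416 and 8499, and 1063, 2994 and 752 for the differences. The main fit had 813, 2687 and 562 for the differences.

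A count test was not run, because whole reads could not be recovered from the FPKM, and a fit to only the groups compared is the same fit for the tissue comparison. Depth is not stated, so the limits it sets on genes near 0 cannot be given.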

Other observations

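The test of other splits was planned, and the tallies of shared genes were chosen after the data were seen. In the ovary between day 5 and day 9 single transcripts of the hemocyte, ecdysone response and neuron lists changed, while none of these lists passed as deposited. Hemocytin (MSTRG.6731), a clotting protein of hemocytes, fell from 20.97 ± 0.707 to 2.464 ± 0.343 FPKM (-2.67 ± 0.23), and the gene with the products clavesin-1 and peroxidasin (MSTRG.1325), the latter of the extracellular matrix, by 3.45, with 4 of 10 hemocyte markers lower and 0 higher (4 and 0 adjusted over the list alone; adjusted p 0.206). Ecdysone-induced protein 75B (MSTRG.6921), a nuclear receptor, rose by 2.07 ± 0.38 and the receptor FTZ-F1-like (MSTRG.1549) fell by 1.41, with 8 of 18 ecdysone response genes higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p 0.0776 as deposited, 0.142 under median-of-ratios scaling, 0.0064 under quantile normalization and 0.558 with an estimated correlation). CUGBP Elav-like members 4 (MSTRG.8542, 1.78 ± 0.17) and 6 (MSTRG.8653, 1.52 ± 0.23), RNA-binding proteins held in the neuron list, rose, while that list had 4 of 16 higher and 3 lower (4 and 3 adjusted over the list alone), a median of -0.21 that turned to 0.30 under quantile normalization and an adjusted p of 0.411. Muscle markers moved beside these, 21 of 32 lower.

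Genes called in both tissues moved the same way more often than independent calls would give in each step, which was not tested. From day 1 to day 5, 120 genes were higher and 469 lower in both, where independent calls would give 28.8 and 179, while 35 were higher in the ovary and lower in the fat body and 17 the reverse, against 81.3 and 63.4. From day 5 to day 9, 143 were higher and 280 lower in both, against 78.5 and 137.9, and opposite moves numbered 31 and 126, against 79.5 and 136.2. From day 9 to day 13 the numbers were 5 and 40, against 2.9 and 14.4, and opposite moves were more frequent than independent calls would give too, at 10 and 8 against 9 and 4.6.

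The other splits asked whether random groups of libraries called as many genes as the tissues did. In fits with 2 groups of 8 libraries, with age left out, the real split called 6893 genes. Of 100 splits 1, the real one, called as many, and the highest of the others called 1. Each other split mixed the tissues, which the first principal component set apart, so low counts there were largely fixed in advance. The result shows no more than that the libraries differ by tissue or by anything that went with it.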
